A study of Mus musculus with 4 samples.

How the data were processed

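The series holds 4 single-cell RNA-seq libraries of adult mouse testis, 1 library per group. The groups are wild-type C57BL/6 mice (WT), mice carrying the W and Wv alleles of the receptor gene Kit (W), and mice of that genotype 3 days (W3) or 5 days (W5) after busulfan, an alkylating drug toxic to spermatogonia. Per the labels, the testis was minced, digested with collagenase type IV, passed through a nylon mesh and loaded on the 10x Genomics Chromium platform with version 2 chemistry, with 10000 cells targeted per sample. The source field of the W sample reads WT, while its title and genotype name the mutant; it was taken as the mutant, and it held 0 spermatocyte-like and 0 spermatid-like cells. Such libraries read the 3' ends of polyadenylated transcripts. They hold no nuclei or protein, and cells that are large or fragile, such as adult Sertoli cells, can be lost in digestion and loading.

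The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 3.0.1 against the mouse genome build mm10. Both the file headers and the submitters' list of tools name Cell Ranger 3.0.1, and that list also names Seurat 3.0.1, whose output was not used here. The settings of the cell calling are not given in the sources used here. The 4 matrices share 1 set of 31053 genes in the same order, and every value is a whole number. A pooled matrix of the 4 libraries was not used, since the separate matrices hold all UMIs of each library. No cell annotation by the authors was used here, so the classes below were rebuilt and can differ from those of the study.

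The files hold 16568 barcodes in WT, 21043 in W, 21945 in W3 and 20118 in W5, against the 10000 cells targeted. Total UMIs were 300745518, 40361886, 30908411 and 41314322 in that order. The lowest UMI count of any barcode was 4193 in WT and 526, 528 and 638 in the other libraries, so the files themselves leave out shallow WT barcodes that were kept in the mutants. Barcodes were kept from 500 UMIs and 200 genes and up to 20% mitochondrial UMIs. The mitochondrial limit removed 70 barcodes of WT (0.423%), 12502 of W (59.4%), 13246 of W3 (60.4%) and 11860 of W5 (59.0%), and 16498, 8535, 8698 and 8258 cells remained. The median UMI count of these cells was 9051 in WT, 3201 in W, 2034 in W3 and 3043.5 in W5. W, W3 and W5 shared 516, 483 and 466 barcodes with WT, against 472.9, 493.1 and 452.1 given by chance from the barcode list of the kit.

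Doublets were sought with Scrublet, run on each library. With its automatic threshold it called 0 cells in all 4 libraries, although the score was higher in some mixed clusters (median 0.455 in cluster 21 and 0.264 in cluster 19) than in Leydig-like cluster 0 (0.132). No other threshold was set, so no cell was removed as a doublet. Clusters that carried markers of 2 classes were set apart as mixed instead. They held 213 cells of WT, 609 of W, 469 of W3 and 496 of W5. Removing the 10% of cells with the highest doublet score per library was tried as an alternative.

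Counts were scaled per cell and log-transformed, 2000 variable genes chosen within libraries gave 30 principal components, and a graph of 15 neighbors was clustered with the Leiden algorithm at resolution 1.0. The 4 libraries were clustered together without batch correction. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Clusters were named "like" a cell type from marker sets fixed before the data were examined. The thresholds that turn marker levels into names, and the rule that sets mixed clusters apart, were chosen after seeing the data. Insl3, Prlr and Hsd17b3 led Leydig-like cluster 0, and Klk1b27, Klk1b24 and Klk1b21 led Leydig-like cluster 17. Ccl8, F13a1 and C1qc led macrophage-like cluster 8, and Spp1, Ccl12, Fn1 and Arg1 led macrophage-like cluster 20. Cldn5 and Ly6c1 led the endothelial-like clusters, Dcn and Gsn the stromal fibroblast-like cluster, and Ccl5, Cd3g and Nkg7 the T or NK-like cluster. Sertoli-like cells of the mutants fell in cluster 1 (Cdh2, Hk2), cluster 3 (Wfdc18, Edn1) and cluster 14 (Rhox8, Defb36), and those of WT in cluster 9 (Cst9, Cst12, Aard). Bc1 and Tuba3a led the spermatogonium-like cluster of W and W3, and Crabp1, Uchl1 and Dazl that of WT.

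Peritubular myoid cells could not be compared as a class. Their markers led mixed clusters 24 and 27, which together held 210 cells of WT, 152 of W, 78 of W3 and 73 of W5 (1.27%, 1.78%, 0.897% and 0.884% of kept cells). A further cluster of 20, 2 and 2 cells in W, W3 and W5, led by immunoglobulin genes, stayed unnamed.

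With 1 library per group there is no replicate, so no test between groups is possible, and no p-value or count of changed genes is given. UMIs were summed over the cells of a class in a library and divided by the class total, in the unit CPM that is usual for count data. Levels carry exact Poisson intervals, ratios exact conditional Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. These cover counting error only, not the difference between animals or preparations. Some counts of 0 are given with the limit that 3 counts would set. Where it is not given, 3 counts would be 2.34 CPM in WT endothelial-like, 4.57 in W5 endothelial-like and 0.343 in WT Sertoli-like cells. Classes were compared where both libraries held at least 50 cells, and genes where one library held a summed count of at least 30.

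Genes were named by a rule fixed before the data were examined, as were the markers, 21 gene lists, comparisons and most alternatives. Per comparison and class it takes, among genes with at least 50 CPM in the higher library and at least 0.5 times the level of all other cells there, the 3 with the highest and the 3 with the lowest ratio by the bound nearest to 1, from a ratio of 2. Mitochondrial, ribosomal and predicted genes are not named by it, and the values of some list members are not reported here. Because free spermatid RNA in WT passes that background rule, a stricter form at 2 times the level of other cells was added after seeing the data. It is used for W against WT, where Rhox8, Etd, Bex2 and Apoc1, named by the first form only, are given as background. Some genes that the stricter form ranks, such as Slc7a5 in endothelial-like cells, are not given. Many genes that lead a cluster are named as such, and where a fold is given for one it describes the class and is no independent result. The same holds for leading genes not named so, such as Cyp11a1 and Hsd3b6 (cluster 0) and Cyp17a1 (clusters 17 and 29). For each list the median log2 ratio of its measured members is given with its percentile among 10000 random lists of the same size matched on expression, as a description of these libraries. The lists described are those with at least 5 measured members, a median of at least 0.4 in size and a percentile up to 2.5 or from 97.5, with most members above the background rule. That rule for description was chosen after seeing the data, and single members of other lists that the text names (such as Stra8, Rhox13, Gdnf, Zmat3, Cyp11a1, Star, Hsd3b6 and Cyb5a) were chosen after their values were seen. Reads from near-identical genes (the Klk1b family, Hist1h2ap and Hist2h2aa1, H2-Q4, Dynlt1f, Rnaset2b) may be assigned to the wrong copy.

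The intervals and list percentiles were tested on simulated class sums. Both libraries were drawn as Poisson counts from 1 profile, after 200 genes of the first library were changed by known folds. The intervals assume such counts, so coverage near 95% follows from the setting. Differences between cells of a class, and genes that vary together, were not simulated. Intervals held the true ratio for 95.6% of 10518 genes at the depth of W5 against W in Leydig-like cells, 96.2% of 5629 genes for W3 against W in endothelial-like cells and 96.2% of 4298 genes in spermatogonium-like cells. Among unchanged genes the interval left out 1 for 14.6%, 4.16% and 4.24% in that order, since the genes changed in the simulation also move the total, so an interval beside 1 alone is weak evidence at the depth of Leydig-like cells. Of 100 unchanged lists each, 5, 7 and 5 fell outside the central 95%. The alternatives were other UMI, mitochondrial and doublet filters, other Leiden resolutions, libraries clustered alone, TMM and median-of-ratios scaling, thinning of each cell to 1000 UMIs, equal weight per cell, other count minimums, totals without mitochondrial genes, and leaving out barcodes shared with WT. Those added after seeing the data were no mitochondrial filter, removal of the highest doublet scores, gene lists and named genes with libraries clustered alone, the stricter background rule and Leydig-like cluster 0 alone.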

Results

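Whole testicular cells of adult mice were profiled by droplet single-cell RNA-seq in 4 libraries. WT came from wild-type C57BL/6 mice, W from mice with the W and Wv alleles of Kit, and W3 and W5 from such mice 3 and 5 days after busulfan. Kit encodes the receptor for Kit ligand, which differentiating germ cells need, and mice of this genotype lose most of their germ cells. The libraries held 300745518 UMIs in WT, 40361886 in W, 30908411 in W3 and 41314322 in W5, over 16568, 21043, 21945 and 20118 barcodes. After filtering 16498, 8535, 8698 and 8258 cells remained, with a median of 9051, 3201, 2034 and 3043.5 UMIs. Each group is 1 library, so there are no replicates, no difference was tested between groups, and the 95% intervals in parentheses cover counting error only.

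By its title the series is about the niche of spermatogonial stem cells, in normal testis and during recovery. W against WT addresses the genotype in animals without busulfan. W3 against W and W5 against W address the time after the drug, and because both use the same W library, W5 against W3 is given as well. Levels are UMIs summed over the cells of a class and given as CPM, and a ratio names the library that was higher.

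Kit (ENSMUSG00000005672; mm10, chromosome 5, 75574916 to 75656722, plus strand) was read first because it is the mutated gene. The 3' tags do not read the W and Wv alleles, so its level checks nothing about the genotype. Over all barcodes Kit stood at 3.18 CPM in WT (2.98 to 3.38), 33.5 in W (31.7 to 35.3), 44.1 in W3 (41.8 to 46.5) and 39.0 in W5 (37.1 to 40.9). Leydig-like cells, the androgen-producing cells between the tubules, held 60.8 CPM in WT (48.5 to 75.3), 103 in W (96.6 to 111), 139 in W3 (129 to 149) and 106 in W5 (99.3 to 113). Spermatogonium-like cells held 26.8 CPM in WT (22.3 to 31.9), 20.4 in W (12.1 to 32.2) and 13.4 in W3 (4.35 to 31.2), with intervals that overlap. The W and W3 intervals overlap those of classes that can hold free Leydig RNA, in which Sertoli-like cells held 12.1 and 17.9 CPM and endothelial-like cells 16.3 and 29.9 in W and W3, against 1.49 and 3.90 in WT. WT spermatids and spermatocytes, which make up most WT barcodes, held between 1.47 and 4.40 CPM.

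Germ cell classes made up 88.0% of kept WT cells (Clopper-Pearson interval 87.5 to 88.5). They included 1535 spermatocyte-like, 3315 round spermatid-like and 4013 elongating spermatid-like cells, and 5290 germ cells of a stage that was not named. None of these later classes was found in W, W3 or W5, where each germ cell was spermatogonium-like. Spermatogonium-like cells were 370 in WT (2.24% of kept cells, 2.02 to 2.48), 109 in W (1.28%, 1.05 to 1.54) and 89 in W3 (1.02%, 0.823 to 1.26). W5 held 0 of 8258 cells, with an upper bound of 0.0447%, where 3 cells would be 0.0363%. The W share was 0.569 times that of WT (0.456 to 0.707), and the W3 share 0.801 times that of W (0.599 to 1.07). WT spermatogonia fell in cluster 22 and those of W and W3 in cluster 26, and the mitochondrial limit removed 59.4% of W barcodes against 0.423% of WT, which sets these shares in part: without it W held 178 such cells of 21037, W3 110 of 21944 and W5 0 of 20118. At a limit of 10% spermatogonium-like cells were 2.61% (2.37 to 2.87) of WT, 3.20% (2.51 to 4.01) of W and 2.79% (2.01 to 3.77) of W3, so at that limit the 3 intervals overlap and W is not below WT. At resolution 0.5 and with no mitochondrial filter 1 and 0 cells of WT had this name, so the order of W and WT for this class depends on the settings. Germ cells of all classes were 88.1% of WT at 10%.

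Spermatogonium transcripts over all barcodes, counted without filters, were lower in W5 than in W for each of 7 markers. From the 15 preset markers these were chosen for being at least 10-fold enriched in spermatogonium-like cells of W, on at least 30 UMIs. Of the others Ret, Id4 and Etv5 were 1.48, 1.21 and 1.15 times W in W5. Gfra1 and Uchl1 were 0.0558 and 0.814 times W, Rhox13 and Esx1 had 0 UMIs in W5, and Prss50 had 0 in both. Stra8, which retinoic acid induces before meiosis, had 436 UMIs in W, 95 in W3 and 3 in W5, and the W5 to W ratio of its CPM was 0.00672 (0.00138 to 0.0198). Crabp1, a retinoic acid binding protein, had 258, 91 and 2 UMIs. The stem and progenitor genes Sall4 and Lin28a, at 109 and 61 UMIs in W and 82 and 27 in W3, had 0 in W5, where 3 counts would be 0.0726 CPM. Zbtb16 was less different, with 266, 188 and 175 UMIs, and Nanos3 had 134, 107 and 27. Together the 7 markers enriched in these cells stood at 34.3 CPM in W (32.5 to 36.2), 20.9 in W3 (19.4 to 22.6) and 5.76 in W5 (5.05 to 6.54). At least 3 of the 7 were seen in 67 kept cells of W, 29 of W3 and 0 of W5. With cells thinned to 1000 UMIs these counts were 3, 3 and 0, which does not tell any of the 3 libraries apart. Among the 2787 Sertoli-like cells of W, with all UMIs, the count was 0. This is no independent check, since the 7 were chosen by enrichment against all other W cells.

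**Figure D1:**
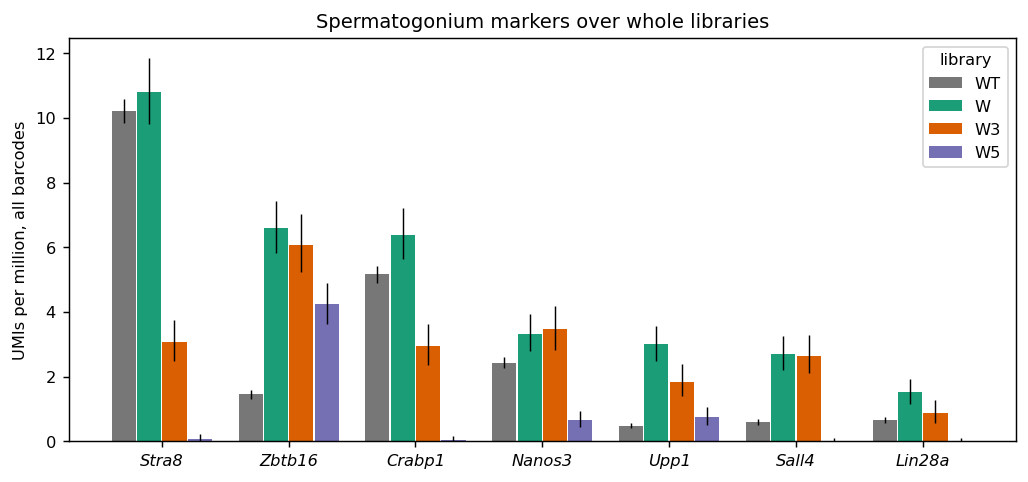
Level of 7 spermatogonium markers over all barcodes of WT, W, W3 and W5, in UMIs scaled to the library total (CPM). The 7 were chosen for enrichment in spermatogonium-like cells of W, and bars are 95% Poisson intervals. Stra8 stood at 10.8 CPM in W, 3.07 in W3 and 0.0726 in W5.

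Among named somatic cells (1762 in WT, 7797 in W, 8138 in W3, 7760 in W5), Leydig-like cells were 7.15% in WT, 30.2% in W, 34.8% in W3 and 39.0% in W5. Sertoli-like cells, which nurse germ cells inside the tubules, were 77.0%, 35.7%, 42.6% and 41.7%. T or NK-like cells were 5.98% in W, 1.40% in W3 and 2.09% in W5, so that the W share was 4.27 times that of W3 (3.47 to 5.28). Stromal fibroblast-like cells were 13.4% in W, 5.25% in W3 and 7.01% in W5, and 0 of the 1762 in WT. Endothelial-like cells were 6.40%, 4.52% and 3.34% in W, W3 and W5, and macrophage-like cells 7.23%, 10.8% and 6.65%. The lowest UMI count of any WT barcode, 4193, lay above the median depths of most mutant classes. These were between 910 and 1614 UMIs in stromal and T or NK-like cells, and at most 3302.5 in Leydig-like, macrophage-like and endothelial-like cells. Sertoli-like cells had medians of 2441.5 UMIs in W3 and 3512 in W5, and 4342 in W. All shares also rest on the same total, so WT shares of these classes, Sertoli-like included, are not comparable with the mutants. At a mitochondrial limit of 10% the W3 to W ratio of the Leydig-like share was 0.747 in place of 1.15 and that of the macrophage-like share 0.626 in place of 1.49, and the endothelial-like ratio was 1.01 in place of 0.707 with no such limit. The T or NK-like ratio of W3 to W, 0.234, was 0.130 at the 10% limit and 0.457 with no limit, and that of W5 to W, 0.349, was 0.724 and 0.788. The stromal ratios of W3 and W5 to W, 0.391 and 0.522, were 0.698 and 0.896 with no limit, and that of W3 was 0.213 at a minimum of 1000 UMIs.

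**Figure D2:**
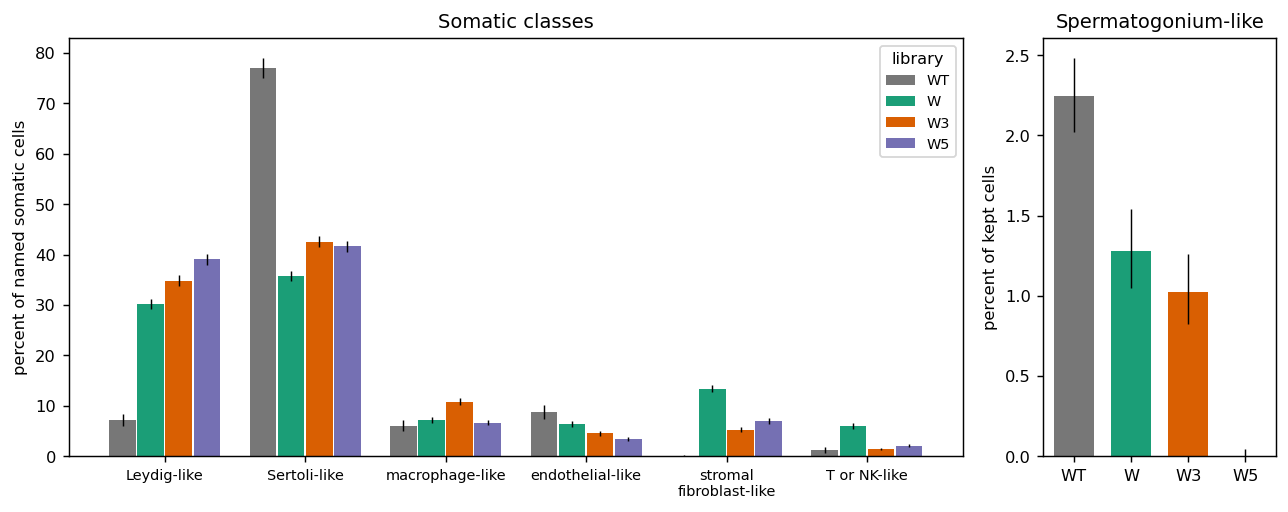
Left, percent of named somatic cells in each of 6 classes; right, percent of kept cells that were spermatogonium-like; bars are 95% Clopper-Pearson intervals, for WT, W, W3 and W5. T or NK-like cells were 5.98% in W against 1.40% in W3, and spermatogonium-like cells were 0 of 8258 in W5.

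W against WT compares the genotypes, and here each class sat in different clusters in the 2 libraries. WT somatic classes also held free spermatid RNA: Prm1, which packs sperm DNA, had UMIs in 100% of WT Leydig-like and Sertoli-like cells, and 18 spermatid markers took 2.97% of the UMIs of WT Leydig-like cells and 7.58% of those of WT Sertoli-like cells, against at most 0.0037% in any mutant class. The median log2 ratio over all genes was 0.18 in Leydig-like, 1.00 in Sertoli-like, 0.55 in macrophage-like, 0.13 in endothelial-like and -0.19 in spermatogonium-like cells, and with TMM scaling it was 0.20, 0.09, 0.05, -0.27 and -0.46. The medians of gene lists below read against these shifts.

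Spermatogonium-like cells of W held more transcript of undifferentiated spermatogonia than those of WT. Of 9 measured members of that list 7 were at least 1.5-fold higher in W and 0 lower, with a median log2 ratio of 1.58. Nanos3, an RNA-binding protein of early germ cells, was 3.40-fold higher (2.46 to 4.66; 75.9 against 22.4 CPM), Lin28a 3.31-fold and Ret, a receptor subunit for GDNF, 3.04-fold. Etv5 was 7.04-fold higher, but its 46.5 CPM in W did not exceed the 47.7 of all other W cells. Nanos3, Lin28a, Ret and Etv5 are also among the markers that name the class. The cells of W and WT sat in separate clusters, so the values compare clusters and not matched stages. At resolution 0.5 and with no mitochondrial filter the WT class held 1 and 0 cells, so the comparison could not be made there. Genes of differentiating spermatogonia went both ways: the homeobox gene Esx1 was 11.7-fold higher in WT (5.63 to 29.3; 92.8 against 7.93 CPM), Rhox13 5.10-fold higher in WT, and the protease gene Prss50 had 109 CPM in WT and 0 UMIs in W, where 3 counts would be 3.40 CPM. Tbx1 was 22.8-fold higher in WT (6.25 to 190) on 2 UMIs in W. Stra8 (374 against 192 CPM), Sohlh1 (256 against 125) and Upp1 (56.6 against 23.8) were instead higher in W. All 6 measured interferon response genes were higher in W with a median of 3.28, led by Xaf1 (72.2-fold, 33.7 to 185; 108 against 1.49 CPM), although 2 of the 6 were at background levels. Of 13 unfolded protein response genes 8 were at least 1.5-fold lower in W, among them Herpud1 (8.32-fold higher in WT) and the chaperone Hspa5 (1.99-fold). The non-coding RNA Bc1 leads the cluster of W and W3, and Olfr889 was 57.7-fold higher in W.

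Leydig-like cells of W held less transcript of immediate early and heat shock genes, which respond fast to stimulation and to tissue handling. Of 15 measured members 12 were at least 1.5-fold lower in W, with a median of -1.15. Fos was 4.38-fold higher in WT (163 against 37.2 CPM), Btg2 6.39-fold and the heat shock gene Hspa1a 5.51-fold. In Sertoli-like cells this list went the other way, with 14 of 17 members at least 1.5-fold higher in W and a median of 3.92. All genes of that class were shifted by 1.00, and 18 spermatid markers took 7.58% of its WT UMIs. Sct, which encodes secretin, was 20.2-fold higher in W (10.6 to 44.3; 132 against 6.52 CPM) and Ogdhl, a relative of a mitochondrial dehydrogenase, 13.9-fold (7.01 to 32.3). Fetub, a secreted protease inhibitor, was 54.3-fold higher in WT (27.3 to 123; 60.1 against 1.11 CPM). Steroidogenic genes went both ways: Cyp17a1, an enzyme of androgen synthesis, was 2.12-fold higher in WT, the luteinizing hormone receptor gene Lhcgr 2.43-fold higher in W, and Cyp11a1 stood at 1057 CPM in W and 1005 in WT. Extracellular matrix genes had a median of 2.04, with 13 of 15 members at least 1.5-fold higher in W, such as Col1a2 (7.58-fold) and Col3a1 (5.35-fold), beside 0 stromal fibroblast-like cells in WT and 1047 in W, although a mixed cluster with peritubular myoid and stromal fibroblast markers held 150 cells of WT and 29 of W. Insl3 leads the Leydig-like cluster of the mutants, and Sult1e1 and Klk1b27 lead cluster 17.

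Endothelial-like cells of W had higher levels of antigen presentation genes. All 7 measured MHC class II genes were at least 1.5-fold higher, with a median of 2.79; Cd74, the invariant chain, was 8.54-fold higher (1298 against 152 CPM), H2-Aa 7.91-fold and H2-Eb1 8.96-fold. Of 12 interferon response genes 9 were at least 1.5-fold higher (median 1.23), among them the ubiquitin-like Isg15 (5.39-fold) and Ifi27l2a (3.98-fold). Glycam1, a mucin of lymph node venules, was 52.9-fold higher in W (14.3 to 442) on 2 UMIs in WT, and Ly6d had 56.9 CPM in W and 0 UMIs in WT. Serpina1e was 26.7-fold higher in WT (8.78 to 132) on 3 UMIs in W. Niche ligands were higher for 7 of 8 members, as Vegfa was 6.00-fold, and matrix genes for 11 of 13. Rhox8, Etd and Bex2, at 101-fold, 39.6-fold and 74.3-fold, were higher in W as well but stood below their level in all other cells of W.

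Macrophage-like cells of W had higher levels of inflammatory cytokine and chemokine genes, with 7 of 9 measured members of that list at least 1.5-fold higher and a median of 2.63. The monocyte attractants Ccl7 and Ccl2 were 11.0-fold and 7.65-fold higher, while Ccl3 was 1.71-fold higher in WT (65.3 against 38.1 CPM). Hspa1a was 8.09-fold higher in WT (5.77 to 11.6) and the phosphatase gene Dusp1 4.08-fold. Apoc1, an apolipoprotein, was 687-fold higher in W (190 to 5679) on 2 UMIs in WT, but at 1576 CPM it stood below the 1631 of all other W cells. MHC class II genes had a median of -0.31 in these cells, with 4 of 6 intervals below 1. Mixed cluster 25, led by Cd74 and H2 genes, held 174 cells of W and 0 of WT and was left out of this class. WT macrophage-like cluster 30 had Cd74, H2-Aa and H2-Eb1 among its leading genes, so this median may not compare like cells. Spp1, Arg1, Fn1 and Ccl12 lead macrophage-like cluster 20 of the mutants, and Cd209f leads cluster 8. Sertoli-like cells of W had all 18 measured Sertoli function genes above WT with a median of 3.25, and of the niche ligands Kitl was 10.7-fold higher (84.2 against 7.89 CPM) and Gdnf 21.9-fold (8.36 to 81.8), while all genes were shifted by 1.00 and the WT cells held 7.58% spermatid marker UMIs. The spermatid gene Prm2 stood at 24825 CPM in these WT cells, above the 18541 of all other WT cells, most of them germ cells. Of the 11 measured niche ligands 6 were at background levels. These folds therefore do not separate the genotype from free RNA. Wnt4 (115 CPM) and Ildr2 (61.8 CPM) had 0 UMIs in the 1357 WT Sertoli-like cells, and Wfdc18 leads cluster 3 of the mutants. Genes encoded by mitochondrial DNA had medians of 1.23 in Leydig-like, 2.72 in macrophage-like, 2.89 in endothelial-like and 1.19 in spermatogonium-like cells. The median mitochondrial share of kept cells was 0.515% in WT and 12.6% in W, and that of all barcodes 0.52% and 24.4%. The WT values are mostly those of germ cells, with 0.161% in elongating spermatid-like cells. By class the medians in WT and W were 5.67% and 11.6% in Leydig-like cells. They were 1.76% and 13.3% in macrophage-like and 1.51% and 12.5% in endothelial-like cells.

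The other lists that met the rule for description in W against WT are given as medians, since free spermatid RNA in WT and free somatic RNA in W enter them. In Sertoli-like cells they were 4.06 for undifferentiated spermatogonium genes, 5.17 for cytokines, 3.64 for smooth muscle genes, 2.80 for retinoid metabolism and -3.20 for the cell cycle. In macrophage-like cells they were 5.18 for extracellular matrix, 1.66 for glycolysis, 3.96 for retinoid metabolism, 1.88 for oxidative stress genes and -4.42 for the cell cycle, where Ccnb1 and Ccnb2, which germ cells also express, stood at 160 and 183 CPM in WT. Endothelial-like cells had 2.58 for cytokines, 1.51 for niche ligands, 1.54 for extracellular matrix and 1.22 for oxidative stress genes, and Leydig-like cells 1.53 for smooth muscle genes. Spermatogonium-like cells had 1.71 for extracellular matrix and 0.76 for cholesterol synthesis, the latter -0.46 with cells thinned to 1000 UMIs.

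W3 against W addresses day 3 after busulfan. MHC class II genes were lower in W3 in each class in which they were measured. In endothelial-like cells all 7 measured members were at least 1.5-fold lower, with a median of -3.14: Cd74 was 9.28-fold higher in W (7.50 to 11.6; 1298 against 140 CPM), H2-Eb1 10.7-fold (6.05 to 21.0) and H2-Aa 9.49-fold. In macrophage-like cells all 6 were lower with a median of -2.05, among them H2-Aa (6.52-fold higher in W, 5.56 to 7.67; 836 against 128 CPM), H2-Eb1 (5.16-fold) and Cd74 (4.58-fold), a median that was -0.23 at a mitochondrial limit of 10%. H2-Q4, whose reads cannot be told from those of its close relatives, was 8.70-fold higher in W. The other classes, where most or all members were at background levels, had medians of -1.66 in Leydig-like, -1.44 in Sertoli-like, -1.17 in stromal fibroblast-like, -1.22 in spermatogonium-like and -0.64 in T or NK-like cells. In Leydig-like cells H2-K1, an MHC class I gene, was 2.25-fold higher in W, at 192 CPM against 310 in all other W cells. H2-Eb1 in endothelial-like cells of W, at 203 CPM, was also no higher than in all other W cells.

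Other endothelial and immune genes were lower in W3 too. Ly6d had 0 UMIs in endothelial-like cells of W3, where 3 counts would be 4.72 CPM, and 56.9 CPM in W. Of 12 interferon response genes in these cells 5 were at least 1.5-fold lower and 0 higher (median -0.48), such as the chemokine gene Cxcl10 (4.82-fold higher in W) and the antiviral gene Bst2 (2.20-fold). Plekho2, Rap2b and Larp4 were 2.75-fold, 2.56-fold and 2.51-fold higher in W3, each on fewer than 50 UMIs, and Rap2b and Larp4 at about their level in all other cells. In macrophage-like cells Ifi27l2a, an interferon-induced gene, was 3.70-fold higher in W3 (3.23 to 4.26; 657 against 178 CPM). Of 14 immediate early and heat shock genes 9 were at least 1.5-fold lower (median -0.74), as Btg2 was 2.64-fold and Fos 1.90-fold higher in W. Of 9 cytokine and chemokine genes 4 were lower (median -0.53), with Ccl7 3.45-fold and Ccl2 2.59-fold higher in W. Clusters 8 and 20 of the mutants made up this class in unequal parts, and no value was taken within each cluster, with 401 and 163 cells in W, 734 and 141 in W3 and 404 and 112 in W5. S100a6, a calcium-binding protein that also leads the T or NK-like cluster, was 2.54-fold higher in W3 but 0.984 times W at a mitochondrial limit of 10%.

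Spermatogonium-like cells of W3 (89, against 109 in W) had lower levels of Stra8, which was 2.59-fold higher in W (1.94 to 3.52; 374 against 145 CPM). Ptcra was 6.55-fold higher in W (4.44 to 10.1; 474 against 72.3 CPM), Unc13d 4.67-fold (3.05 to 7.51) and Retn 12.5-fold (3.31 to 106) on 2 UMIs in W3. Ddit4, a stress-induced inhibitor of mTOR, was 3.03-fold higher in W3 (1.86 to 4.97; 110 against 36.3 CPM) and the laminin gene Lamb1 3.29-fold (1.97 to 5.55). The median of 7 undifferentiated spermatogonium genes was 0.00.

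Leydig-like cells of W3 had Ogdhl 2.25-fold (2.04 to 2.48; 181 against 80.5 CPM) and C1qtnf6 2.22-fold above W, the latter below its level in all other cells, while the cytokine receptor kinase gene Jak3 was 3.56-fold higher in W (2.86 to 4.46; 59.6 against 16.8 CPM) and Rnaset2b, which has a near-identical copy, 2.67-fold. Of 7 vascular activation genes 4 were at least 1.5-fold higher in W3 (median 0.60), among them Apln, a vascular peptide (1.84-fold). The p53 targets Zmat3 and Trp53inp1 were 1.78-fold and 1.51-fold higher in W3. The 5 measured genes of undifferentiated spermatogonia had a median of 0.46 in these cells, with Zbtb16, also a regulator in somatic cells, 1.82-fold higher. Sertoli-like cells of W3 had Bc1 2.90-fold, C1qtnf6 2.36-fold and Syngr1 2.29-fold above W. Bc1 was near background there, at 928 CPM against 800 in all other W3 cells. The channel gene Aqp8 was 2.27-fold, Btg3 2.15-fold and Dynlt1f 2.19-fold higher in W, the last with near-identical copies. The 11 measured niche ligands of Sertoli-like cells had a median of 0.11, with 2 at least 1.5-fold higher in W3, such as Pdgfa (1.54-fold), and 2 lower. Of the latter Gdnf, the growth factor for spermatogonial stem cells, was 2.13-fold higher in Sertoli-like cells of W than of W3 (10.0 against 4.71 CPM) and differed little between W and W5 (10.0 against 9.18). Rhox8, a Sertoli transcript present as free RNA, was 2.28-fold and 2.18-fold higher in Leydig-like and macrophage-like cells of W3.

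In stromal fibroblast-like cells W was higher than W3 for Tpm4, an actin-binding tropomyosin (5.60-fold, 2.11 to 21.0; near its level in other cells), Tcea3 (3.40-fold) and the matrix gene Smoc2 (2.84-fold). Bc1 and C1qtnf6 were higher in W3 (3.88-fold and 3.66-fold), but Bc1, at 495 CPM against 869 in all other W3 cells, and C1qtnf6, at 81.0 against 79.7, were at or near background. The chemokine gene Ccl21a was 14.6-fold higher in W3 (8.22 to 27.8), on 60 UMIs, but 0.564 times W at a minimum of 1000 UMIs, 0.586 times with high doublet scores removed and 0.844 times with libraries clustered alone. In T or NK-like cells 4 of 8 glycolysis genes were at least 1.5-fold lower in W3 (median -0.40), such as Eno1 (1.75-fold higher in W), a median that was 0.03 with a count minimum of 10.

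W5 against W addresses day 5. Cholesterol synthesis genes were lower together in Leydig-like cells of W5, which use cholesterol to make androgens. Of 16 measured members 12 were at least 1.5-fold lower and 0 higher, all 16 intervals lay below 1, and the median of -0.87 was below those of all 10000 random lists. Hmgcs1, an early enzyme of the pathway, was 2.42-fold higher in W (2.28 to 2.57; 429 against 177 CPM), Mvd 2.19-fold, Cyp51 2.13-fold (187 against 87.6 CPM) and Insig1 1.95-fold. Of 16 steroidogenesis genes, a list below the size set for description (median -0.28), 6 were at least 1.5-fold lower in W5 and 0 higher, with 10 intervals below 1 and 4 above. Cyp11a1 (1057 against 599 CPM) and Star, which imports cholesterol into mitochondria (597 against 374), were 1.76-fold and 1.60-fold higher in W, while Hsd3b6 and Cyb5a were 1.15-fold and 1.16-fold higher in W5.

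Immediate early genes were higher in the same cells of W5. Of 16 measured members 9 were at least 1.5-fold higher and 2 lower (median 0.69): Fosb was 2.77-fold, Dusp1 2.38-fold and Fos 2.31-fold higher (86.2 against 37.2 CPM), while Hspa1a was 1.71-fold higher in W. The median was 0.45 at a mitochondrial limit of 10%. Of 11 interferon response genes 5 were lower and 1 higher (median -0.56), such as Ifi27l2a (1.76-fold higher in W). Jak3 was higher in W at 59.6 against 15.7 CPM (ratio interval 3.15 to 4.61) and Serpina3n, an acute-phase protease inhibitor, 2.43-fold. Klk1b24, Klk1b27 and Klk1b21, close relatives whose reads may be swapped, lead Leydig-like cluster 17, which held 49 cells of W, 155 of W3 and 377 of W5. Of 5 genes of undifferentiated spermatogonia Etv5, also expressed by somatic cells, was 1.55-fold higher in W5 (list median 0.50).

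**Figure D3:**
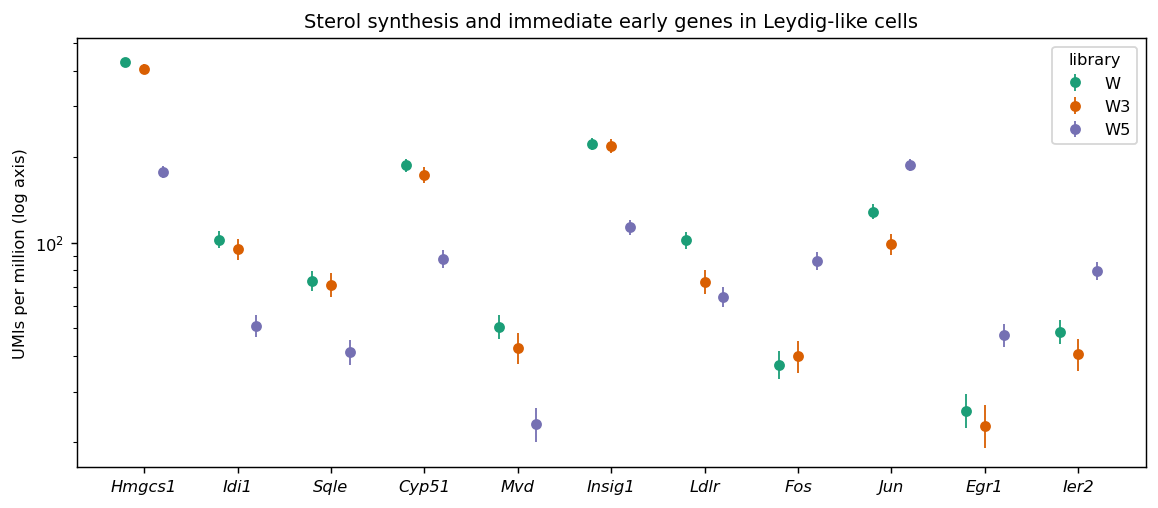
Level in Leydig-like cells, in CPM on a log axis, of 7 cholesterol synthesis and uptake genes and 4 immediate early genes in W, W3 and W5, with bars for 95% Poisson intervals. Hmgcs1 stood at 429 CPM in W, 406 in W3 and 177 in W5, and Fos at 37.2, 39.9 and 86.2 CPM.

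MHC class II genes were lower in W5 than in W in each class in which they were measured. In endothelial-like cells the median of 7 members was -2.04, with Cd74 5.83-fold (4.93 to 6.95; 1298 against 222 CPM) and H2-Aa 4.77-fold higher in W. In macrophage-like cells the median of 6 was -1.28, with H2-Aa 2.77-fold (2.46 to 3.11), H2-Eb1 2.72-fold and Cd74 2.34-fold higher in W. Medians at background levels were -1.06 in Leydig-like, -0.84 in Sertoli-like, -1.27 in stromal fibroblast-like and -0.98 in T or NK-like cells. Cd200, a surface ligand that restrains myeloid cells, was 11.4-fold higher in endothelial-like cells of W (9.54 to 13.7; 2206 against 194 CPM), and Ly6d had 0 UMIs in W5. Bst2 was 2.01-fold higher in W, among 12 interferon response genes with a median of -0.53. Of 7 vascular activation genes Selp, an adhesion receptor for leukocytes, was 3.08-fold and Icam1 2.13-fold higher in W while Edn1 was 1.60-fold higher in W5; their median of -0.53 was 0.23 with cells thinned to 1000 UMIs. Ccl21a was 4.26-fold, the pericyte gene Pdgfrb 2.94-fold and Cytl1 3.24-fold higher in W5, the last 0.0967 times W at a mitochondrial limit of 10%. In endothelial-like cluster 11 of the mutants, pericyte or vascular smooth muscle markers scored second, at 1.72 against 4.06 for endothelial markers. The class may therefore hold pericytes, and no value was taken without them.

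Macrophage-like cells of W5 had Stmn1, which regulates microtubules, 2.48-fold higher (2.02 to 3.05; 233 against 94.0 CPM), and the histone gene Hist1h2ap, one of many near-identical copies, 5.15-fold. Tsc22d3, a glucocorticoid-induced gene, was 2.42-fold higher in W5. The B cell attractant Cxcl13 was 3.95-fold higher in W (2.60 to 6.22; 85.5 against 21.6 CPM), and Ccl8 leads macrophage-like cluster 8. In Sertoli-like cells of W5 the protease inhibitor gene Spink8 was 21.5-fold higher (15.0 to 31.9; 53.1 against 2.47 CPM), while Tnfaip2 and Mid1 were 2.73-fold and 2.76-fold higher in W. Cd52, a lymphocyte gene, was 2.55-fold higher in W5 but stood at 79.9 CPM against 154 in all other W5 cells, a background level. Of 9 cytokine genes there 5 were lower (median -0.65), as Cxcl1 was 1.84-fold and Icam1 1.57-fold higher in W, with 4 members at background level.

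Stromal fibroblast-like cells of W5 had lower levels of niche ligand and matrix genes. Of 8 niche ligands 4 were at least 1.5-fold lower and 0 higher (median -0.62): the growth factor gene Igf1, which also leads this cluster, was 2.03-fold (683 against 336 CPM), Cxcl12 1.90-fold and Kitl 1.68-fold higher in W. Of 15 matrix genes 5 were lower (median -0.41), as Col1a1 was 2.55-fold and Col3a1 1.99-fold higher in W. Cd200 was 2.72-fold, the T cell attractant Ccl19 3.76-fold (2.18 to 6.95) and Plac9b 3.27-fold higher in W, and Jade3, Lrp8 and Cdk19 were 2.90-fold, 2.75-fold and 2.42-fold higher in W5, at levels near or below those of all other cells. The median of 5 cytokine genes was -0.87, and 0.09 with a count minimum of 100. In T or NK-like cells all 5 interferon response genes were lower in W5 (median -0.83), such as Ifi27l2a (1.73-fold higher in W), and Sertoli function genes, which are free RNA there, had a median of 0.59.

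**Figure D4:**
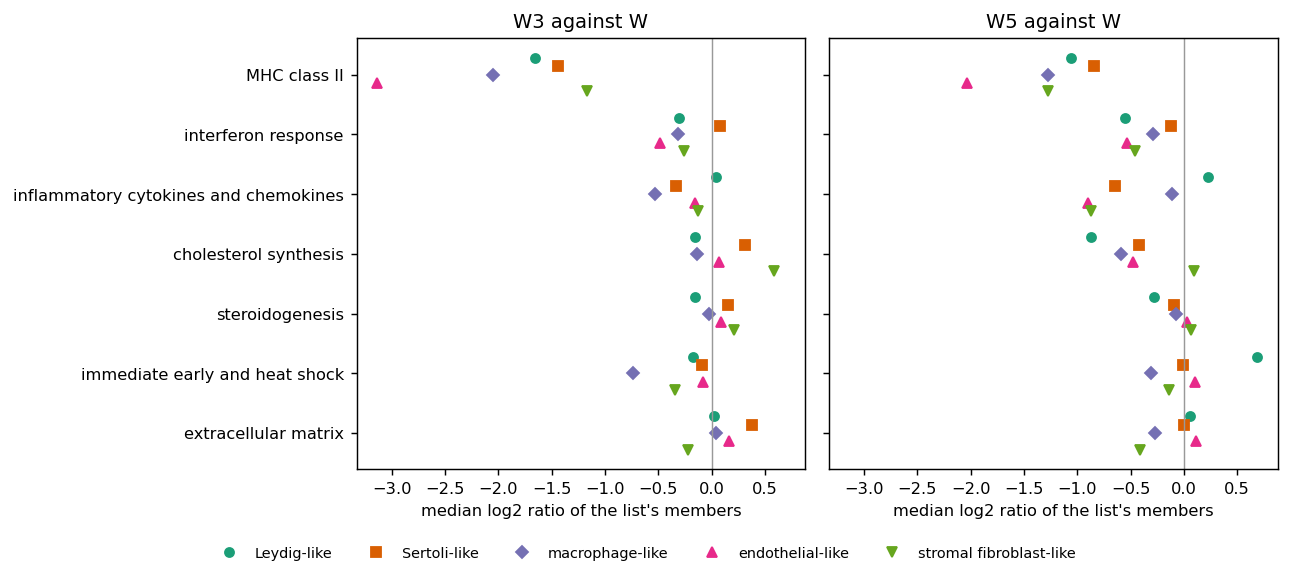
Median log2 ratio of 7 gene lists (vertical axis) in 5 cell classes, for W3 against W and W5 against W, with a line at 0 and no error bars. MHC class II in endothelial-like cells sits at -3.14 and -2.04, and cholesterol synthesis in Leydig-like cells at -0.87 for W5 against W.

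W5 against W3 addresses the step between the 2 times without the shared W library. In Leydig-like cells cholesterol synthesis genes were again lower in W5, with 9 of 16 at least 1.5-fold lower and 0 higher (median -0.75), such as Hmgcs1 (2.29-fold higher in W3) and Cyp51 (1.97-fold). Of 15 p53 targets 7 were lower in W5 and 0 higher (median -0.45), with Zmat3 2.14-fold and the cyclin gene Ccng1 1.97-fold higher in W3. Of 15 immediate early and heat shock genes 11 were higher in W5 (median 0.89), with Fosb 3.41-fold and Fos 2.16-fold higher. Cyp11a1, the first enzyme of steroid synthesis and a marker of the class, was 2.51-fold higher in W3 (1504 against 599 CPM), Serpina3n 3.02-fold and Ly6e 2.30-fold, and Ass1, an enzyme of arginine synthesis, was 2.28-fold higher in W5 (569 against 249 CPM). Of 7 measured cell cycle genes 2 were lower in W5 (median -0.44), as Mcm5 was 2.08-fold higher in W3.

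Sertoli-like cells of W5 had Spink8 59.2-fold (29.9 to 138) above W3, with Cd52, at background level, 3.83-fold. Pgd, an enzyme of the pentose phosphate pathway, was 2.39-fold, Bc1 2.20-fold and Arhgdig 2.11-fold higher in W3. Bc1 was near background, at 928 CPM in Sertoli-like cells of W3 against 800 in all other W3 cells. In macrophage-like cells 3 of 6 MHC class II genes were at least 1.5-fold higher in W5 (median 0.75), such as H2-Aa (2.36-fold), but this median was -0.92 at a mitochondrial limit of 10%. Of the cytokine genes Ccl4 was 3.09-fold higher in W5 (list median 0.42), and Ear2, a ribonuclease of myeloid cells, and Cxcl13 were 3.45-fold and 3.35-fold higher in W3. In endothelial-like cells Cd200 was 6.80-fold higher in W3 (5.64 to 8.26), Uxt 5.85-fold and Scgb3a1 3.93-fold, and Cytl1 was 12.6-fold higher in W5 (5.13 to 40.1). Ccl21a was 4.61-fold higher in W5 there, but 0.0364 times W3 at a mitochondrial limit of 10%. Of 6 niche ligands in endothelial-like cells Csf1 was 2.62-fold and Kitl 1.98-fold higher in W3 (median -0.48). In stromal fibroblast-like cells the collagen genes Col3a1 (190 against 73.0 CPM) and Col1a2, which also leads the cluster, were 2.60-fold and 2.17-fold higher in W3. Ccl5 leads the T or NK-like cluster and is not read as a difference: in macrophage-like, endothelial-like and stromal fibroblast-like cells of W5 it stood at 72.1, 57.9 and 54.2 CPM, below the 92.8, 92.7 and 93.1 of all other W5 cells. Ccl21a was 13.1-fold higher in stromal fibroblast-like cells of W3, a direction that other filters turn (5.31 times W3 at a minimum of 1000 UMIs). Hist2h2aa1, a histone gene with a near-identical copy, was 3.00-fold, 3.08-fold and 3.36-fold higher in Leydig-like, Sertoli-like and stromal fibroblast-like cells of W5, below its level in all other cells in the first and last. Sertoli function genes in T or NK-like cells had a median of 0.45.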

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

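Both results were noted because the sign at day 3 after busulfan was opposite to that at day 5; in each case the difference was not tested. In Leydig-like cells the median log2 ratio of immediate early and heat shock genes was -0.18 in W3 against W and 0.69 in W5 against W. In Sertoli-like cells that of cholesterol synthesis genes was 0.31 and -0.42, where most members lie at or near the level of free RNA.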

How the results depend on the processing

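No paired analysis was possible because each group has 1 library. Alternatives without a mitochondrial filter, without the highest doublet scores, and gene results with libraries clustered alone were chosen after seeing the data. Over all alternatives, 727 list medians stayed within their range, 150 moved and 7 turned sign. For named genes these counts were 1510, 148 and 9, and for shares 140, 35 and 5. The values that stayed include some that could not change. Keeping doublet calls gave 61 list medians, 124 named genes and 22 shares of this kind, and a count minimum of 100 gave 98 named genes. The cause was not tested for any value below.

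At a mitochondrial limit of 10%, ratios that crossed 1 were Ccl21a 0.0364 (endothelial-like, W5 to W3), Cytl1 0.0967 (W5 to W), S100a6 0.984 (macrophage-like, W3 to W), and the shares of Leydig-like 0.747 and macrophage-like cells 0.626 (W3 to W), Sertoli-like cells 0.903 (W5 to W) and macrophage-like cells 1.31 (W5 to W3). The MHC class II median in macrophage-like cells turned to -0.92 for W5 against W3 and that of vascular activation in endothelial-like cells to 0.02 for W5 against W. MHC class II in macrophage-like cells moved to -0.23 (W3 against W) and -0.95 (W5 against W), immediate early genes in Leydig-like cells to 0.45 (W5 against W), the T or NK-like share ratios to 0.130 (W3 to W) and 0.724 (W5 to W), and germ cells to 3.20% in W and 2.79% in W3.

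With no mitochondrial filter the endothelial-like share ratio of W3 to W turned to 1.01. The T or NK-like ratios moved to 0.457 and 0.788 and the stromal ones to 0.698 and 0.896 (W3 and W5 to W), germ cells to 96.7% in WT, 0.846% in W and 0.501% in W3, and MHC class II (W3 against W) to -2.61 in endothelial-like and -1.73 in macrophage-like cells.

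Ccl21a in stromal fibroblast-like cells turned to 0.564 (W3 to W) and 5.31 (W5 to W3) at a minimum of 1000 UMIs, 0.586 and 1.68 without the highest doublet scores, and 0.844 and 1.21 with libraries clustered alone. The stromal share ratio moved to 0.213 (W3 to W, 1000 UMIs) and 0.463 (W5 to W, without the highest doublet scores), and WT germ cells to 88.6% without those scores and 86.7% clustered alone. Counted by at least 3 germ markers, germ cells were 100% of WT, 3.98% of W, 1.70% of W3 and 2.07% of W5, a count that free RNA can fill.

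Thinned to 1000 UMIs, cholesterol synthesis in spermatogonium-like cells (W against WT) turned to -0.46 and vascular activation (W5 against W) to 0.23; with a count minimum of 100 the latter turned to 0.22 and stromal cytokines (W5 against W) to 0.09, and with 10 glycolysis in T or NK-like cells (W3 against W) to 0.027. MHC class II in macrophage-like cells (W3 against W) moved to -2.29 thinned, -2.34 with equal weight per cell and -2.19 with median-of-ratios scaling. Cholesterol synthesis in Leydig-like cells (W5 against W) ran from -0.92 to -0.81. W5 held 0 spermatogonium-like cells under every clustering tried, but with libraries clustered alone this could not be otherwise. Clusters there took the main name most common among their cells, and no W5 cell had this name.

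No value could be had for 39 results at a mitochondrial limit of 10%, which left no stromal class, 25 without that filter, 33 at a count minimum of 100, 12 at resolution 0.5 and 4 thinned. Keeping doublet calls changed nothing, since none was made. Depth limits the spermatogonium-like class of W3 (89 cells, median 3855 UMIs) and genes under 30 UMIs.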

Other observations

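The tests of the mitochondrial filter and of depth in W5, of free MHC class II RNA in each pair of classes and in the trimmed endothelial-like class, and of W5 against W3 for cholesterol genes were chosen after the results were seen; the others had their predictions written before, though the setting of cluster 0 alone was itself added after seeing the data. Several signs of lymphoid cells were more abundant in the W library than in W3 and W5. Immunoglobulin genes led a small cluster of 20 cells in W, 2 in W3 and 2 in W5, and Igkc, the kappa light chain, was seen in 40.8% of Leydig-like cells of W, 6.07% of those of W3 and 5.18% of those of W5 at median depths of 3302.5, 1970 and 2934 UMIs. Leydig-like cells should lack Igkc, so these values describe free RNA in each library. In Sertoli-like cells the percentages were 44.7%, 6.12% and 6.18%. A mixed cluster led by Cd74 and H2 genes with macrophage and T or NK markers held 174 cells of W, 66 of W3 and 83 of W5.

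A small epithelial-like cluster held 36 cells of W, 5 of W3 and 5 of W5, and an erythrocyte-like one 40, 50 and 10. Hbb-bs, a globin gene, stood at 183, 138 and 39.3 CPM in Leydig-like cells of W, W3 and W5 as free RNA. Insl3, a Leydig cell hormone, was seen in W in 64.0% to 75.0% of the Sertoli-like, macrophage-like, endothelial-like, stromal fibroblast-like and T or NK-like cells.

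No spermatogonium-like cell was found in W5, against 105.5 given by the W share. Placement in other clusters is argued against by the sum of markers chosen in W cells, over all barcodes, 0.168 times that of W (0.146 to 0.193). Lower depth is argued against by a median depth 0.951 times that of W. Without the mitochondrial filter W5 held 0 such cells against 170.2 given by the W share, which cannot settle the part of the filter. WT also held 0 of 16568 in that setting, and a cluster made almost only of removed cells could not take a name. The marker sum also counts the barcodes that the filter removed. A loss of these cells by day 5 after busulfan may explain the pattern as a hypothesis. A difference between animals or preparations stays open and was not tested, since each group is 1 library.

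MHC class II genes were lower in W3 and W5 than in W in every class measured, while against WT the W library was higher in endothelial-like cells (median 2.79) and not in macrophage-like cells (-0.31). The macrophage-like value leaves out mixed cluster 25, led by Cd74 and H2 genes, with 174 cells of W and 0 of WT. Cd74 and H2 genes also led WT macrophage-like cluster 30, so this contrast may follow from the naming of clusters. Against WT the medians were also 3.69 in Sertoli-like, 2.355 in spermatogonium-like and 0.062 in Leydig-like cells, where most or all members were at background levels. Free RNA of antigen-presenting cells is argued against as the whole signal of endothelial-like and macrophage-like W cells, whose median level was 1.29 times (1.12 to 1.58) and 3.91 times that of all other cells, while in Leydig-like and Sertoli-like cells the levels of 0.213 and 0.133 times are those free RNA would give. The 10% of endothelial-like cells with most such UMIs held 45.4% of them, which decides nothing where free RNA reaches most cells, but without these cells the class still held 3.55 times (lower bound 3.15) the UMIs per cell of Sertoli-like cells treated alike, against a few antigen-presenting cells with free RNA in the rest. As hypotheses with no test here, a response of vessels and macrophages to busulfan or inflammation in the W library alone could each give the pattern, and so could a difference between animals or preparations; only further W libraries would separate these. In macrophage-like cells the W3 value of -0.23 at a mitochondrial limit of 10% leaves open which macrophages the filter keeps.

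Cholesterol synthesis genes were lower in Leydig-like cells of W5. More cells of cluster 17 is argued against by a median of -0.92 in cluster 0 alone, and a few genes taking most counts by -0.83 with TMM scaling. W standing apart is argued against by -0.75 for W5 against W3. A later response of Leydig cells to busulfan may be the source as a hypothesis. A difference between animals or preparations stays open and was not tested.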
